A study of Homo sapiens with 27 samples.

How the data were processed

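MCF-7 cells, an established human breast carcinoma line, were hybridised to Agilent 1-colour (Cy3) arrays in 3 experiments, per the labels. The TACC3 experiment held 12 mRNA arrays: 4 of cells with a control shRNA and doxycycline, 4 of cells with an inducible TACC3 shRNA without doxycycline, and 4 of the TACC3 shRNA cells after 4 days of doxycycline. The miRNA experiment used the same groups with 1, 3 and 3 arrays. The irradiation experiment held 8 mRNA arrays: 2 of cells that were not irradiated, and 3 each at day 4 and day 6 after 20 Gy. The labels state no day for the non-irradiated cells, and the plating density differed between labels.

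The array files held intensity values from the scanner and their flag columns held other values (0 or 1 for each spot), per the file headers. Feature Extraction 9.5.3.1 had read the TACC3 arrays, 10.1.1.1 the irradiation arrays and 10.5.1.1 the miRNA arrays. On slides 1 and 2 of the TACC3 experiment the extraction used no surrogate values and a well-above-background multiplier of 2.6, and on slide 3, read in a second scan session, it used surrogates and a multiplier of 13. The probe annotation was built on hg17 in the TACC3 files and on hg18 in the others. The deposited series matrix held log2 values made by the authors. Found from the values, its mRNA columns were log2 processed signal minus the array's 75th percentile, then centred on the probe's median within the experiment. Its miRNA columns were log2 of the total gene signal with a floor of 1, minus the 75th percentile, without centring. At least 99.8% of the values of every column lay within 0.01 of that account. The column medians ran from -0.03 to 0.03 in the TACC3 experiment, -0.12 to 0.11 in the irradiation experiment and -3.08 to -2.34 for miRNAs.

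The analysis started from the processed signal of each spot. Spots with an outlier flag were left out (59 to 110 per TACC3 array, 69 to 217 per irradiation array, 895 to 1360 per miRNA array), and at most 1 spot per array was saturated, none of them on a probe of a named gene. Repeated spots of a probe were averaged, log2 was taken, and the array's 75th percentile was subtracted. Each experiment had a floor, the highest over its arrays of the lowest scaled signal well above background: -5.36 (TACC3), -5.11 (irradiation) and -3.45 (miRNA), and lower values were set to it. A probe was kept where it lay well above background on every array of at least 1 group. Of 41000 mRNA probes, 25398 got a symbol through the accession, 2539 through the symbol in the file, 762 through an older symbol, and 12301 got none, besides 93 controls. They covered 18341 symbols. The brightest probe stood for its gene, which left 13527 genes tested in the TACC3 experiment and 14335 in the irradiation experiment. For miRNAs (2405 probes, 868 miRNAs) the log2 probe values were averaged, the 75th percentile was taken over the 194 miRNAs detected on every array, and the 231 miRNAs detected on all arrays of a group of 3 were tested.

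limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3) fitted 1 mean per group over all arrays of an experiment, without pairing or batch term, and two-sided p values were adjusted by Benjamini and Hochberg within each comparison at 0.05. Group values are given ± SD and changes ± the moderated SE. The comparisons were shTACC3 with against without doxycycline, shTACC3 against shControl both with doxycycline, shControl with doxycycline against uninduced shTACC3, each day after irradiation against no irradiation, and day 6 against day 4, with the first 2 repeated for miRNAs. Genes changed the same way against both TACC3 controls form the group called core below. Because both of these comparisons share the induced arrays, the overlap was set against 20 simulated draws with no effect. The 19 mRNA lists and 7 miRNA lists, the settings and the comparisons were fixed before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, then again with an estimated correlation, and with fry as an alternative. The lists were DNA replication, mitosis, p53 targets, secretory factors of senescence, sirtuins, oxidative phosphorylation, antioxidant and NRF2 targets, estrogen receptor targets, luminal identity, interferon-stimulated genes, lysosome, histones, ATF4 and the unfolded protein response, cholesterol synthesis, reported targets of miR-15/16, telomere, nuclear envelope and senescence markers, and markers of fibroblasts, leukocytes and basal or mesenchymal cells, which stand for other cell types. The miRNA lists were the miR-15/16 family, p53-induced miRNAs, miR-17~92 with its paralogs, let-7, senescence-linked miRNAs, the miR-200 and epithelial group, and miRNAs of leukocytes and fibroblasts.

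Named mRNAs came from a rule: TACC3, SIRT1 to SIRT7, CDKN1A, MDM2, MKI67 and LMNB1 always, then the 6 largest rises and 6 largest falls without overlap between the arrays of the groups, then up to 3 members of each list with the largest change past the threshold. For the TACC3 comparisons the largest changes were ranked by the smaller of the changes against both controls. For miRNAs the rule took the miR-15/16 family and miR-34a, the 5 largest rises and falls, and up to 3 members per list. The text prints a part of the genes so named.

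In simulated data with the spread of each comparison, with 200 genes changed (40 miRNAs), the test recovered 71% (TACC3 shRNA with against without doxycycline), 69% (against shControl), 72% (shControl against uninduced), 76% (day 4), 65% (day 6) and 67% (day 6 against day 4) of 1.5-fold changes. It recovered 95%, 91%, 93%, 94%, 92% and 95% of 3-fold changes. For the miRNA comparisons it recovered 75% and 60% at 1.5-fold, and 100% and 85% at 3-fold. False calls made up 3.49%, 3.03%, 2.94%, 9.09%, 2.48%, 1.82%, 5.41% and 0% of the calls in the same order. The list test called the 1 shifted list and 0 others in each of the 6 mRNA simulations. Genes were drawn independently, so correlated genes were not tested. The median SE of a gene was 0.0999 in the TACC3 comparisons, 0.0802 at each day against no irradiation, 0.0716 for day 6 against day 4, and 0.0617 and 0.0873 for the miRNA comparisons.

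Alternatives fixed in advance replaced the scaling (median, quantile or none), the background step (normexp with offset 50), the filter, the choice of probe, the test, the blocking by slide or replicate number, or left out each array in turn, and the deposited matrix was tested too. Others were chosen after seeing the data: scaling to 5 E1A spike-in probes with signal from 100 to 50000, the scan session as a block, the first scan session alone, each slide alone, averages per slide, averages of near-identical arrays, a floor of 1, and the slide row for miRNAs. The labels state no pairing. Arrays of the same number deviated together in all 4 pairs of TACC3 shRNA cells with and without doxycycline (correlations 0.27, 0.22, 0.58 and 0.82), so a fit with the replicate as a block was also run there, and it called 7462 genes against 6727 in the group-only fit. Slide 1 of the TACC3 experiment held shControl 1 and 2 with uninduced 1 and 2, slide 2 held uninduced 3 with induced 1 to 3, and slide 3 held shControl 3 and 4, uninduced 4 and induced 4. The irradiation slides each held 1 non-irradiated array with arrays of both days, and all miRNA arrays lay on 1 slide.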

Results

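This series measured gene expression in MCF-7 breast carcinoma cells with an inducible shRNA against TACC3, a protein of the centrosome and mitotic spindle, and after irradiation. Its title names miR-15b and SIRT4, a mitochondrial sirtuin, in premature senescence, so both were followed through every group. The shRNA was read on 12 mRNA arrays (4 of shControl cells with doxycycline, 4 of uninduced shTACC3 cells, 4 of shTACC3 cells with doxycycline) and on 7 miRNA arrays (1, 3 and 3). Irradiation was read on 8 mRNA arrays (2 without irradiation, 3 at day 4 and 3 at day 6 after 20 Gy). In the irradiation labels the day and the dose stood in each other's field, so the groups were read from the titles. The design text gives 4 independent replicates. Induced 1 and 2 differed by about the spread of repeated spots and may be repeat hybridisations, so n = 4 may stand for 3. shControl 3 and 4 differed beyond that spread. The 75th percentile of signal was 1590 ± 90.7 (SD, n = 4) in shControl, 1560 ± 54.7 in uninduced and 1589 ± 80.2 in induced arrays. It was 1392 ± 22.6 (n = 2) without irradiation, 1195 ± 146 (n = 3) at day 4 and 629 ± 22.7 (n = 3) at day 6, and for miRNAs 233 (n = 1), 258 ± 13.3 (n = 3) and 186 ± 10.3 (n = 3). The share of probes detected ran from 60.3% to 72.7% on TACC3 arrays, from 65.8% to 70.7% on irradiation arrays and from 24.7% to 29.5% on miRNA arrays.

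TACC3 shRNA with doxycycline lowered TACC3 more than 10-fold, lowered genes of mitosis and DNA replication, and raised histone genes, CDKN1A and SIRT4. The list call of mitosis was lost with an estimated correlation in both comparisons, as were those of replication and histones against shControl. TACC3, read by 1 probe on chromosome 4 (1711276 to 1711515, hg18), had a scaled log2 signal of -2.34 ± 0.05 (SD, n = 4) in induced cells, 1.18 ± 0.13 in uninduced cells and 1.25 ± 0.16 in shControl cells. The change was -3.52 ± 0.09 (SE) against uninduced cells (limma adjusted p = 3.13e-10, 11.5-fold lower) and -3.60 ± 0.09 against shControl (adjusted p = 1.69e-10, 12.1-fold lower). CDKN1A, the CDK inhibitor p21, rose by 0.87 ± 0.06 (adjusted p = 3.71e-07) and 1.23 ± 0.06 (adjusted p = 1.85e-08). SIRT4, read by 1 probe on chromosome 12 (119235262 to 119235321, hg18), had a log2 signal of -3.05 ± 0.15 in induced, -4.78 ± 0.16 in uninduced and -5.10 ± 0.30 in shControl cells (n = 4 each). It rose by 1.73 ± 0.14 (adjusted p = 1.47e-06, 3.32-fold) and by 2.05 ± 0.14 (adjusted p = 3.03e-07, at least 4.14-fold, since shControl 3 and 4 lay at the floor).

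**Figure D1:**
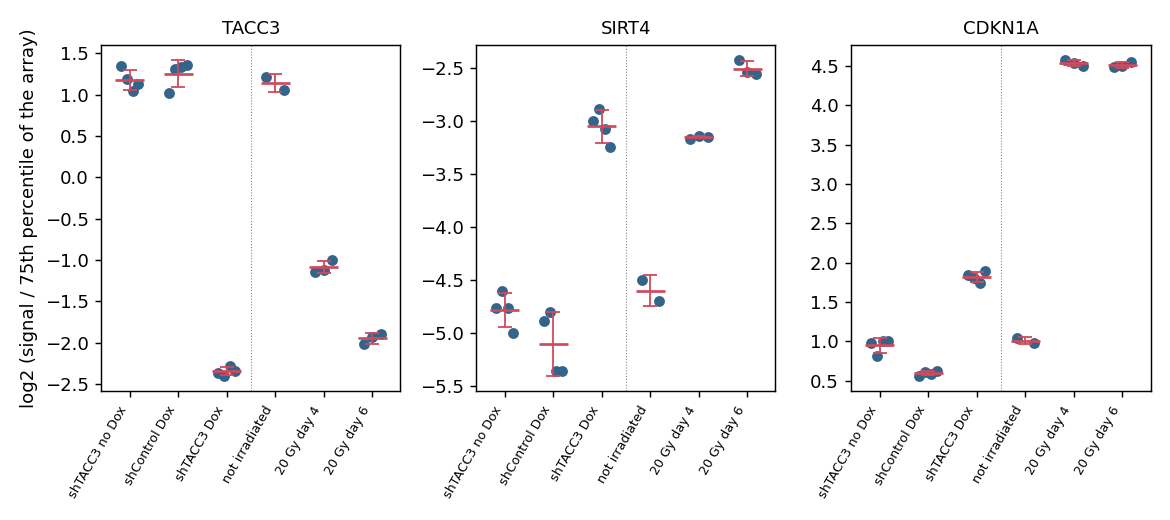
Scaled log2 signal of TACC3, SIRT4 and CDKN1A on every mRNA array. Each dot is 1 array, the wide bar the mean of its group and the whiskers its SD. The dotted line parts the TACC3 experiment from the irradiation experiment, which are scaled separately.

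Against uninduced cells, limma called 6727 of 13527 genes (3375 up, 3352 down), of which 378 rose and 485 fell at least 2-fold. Against shControl it called 7249 (3590 up, 3659 down), 574 and 617 of them at least 2-fold. Called the same way against both controls were 5753 genes, 2785 up (896 expected if independent) and 2968 down (907 expected). Those expected counts ignore the shared induced arrays: without any effect, simulated changes correlated at 0.50 with a covariance of 0.02, where the data gave 0.91 and 0.30. With a different pair of induced arrays in each comparison, 4443 genes (induced 1 and 2 against uninduced cells) and 4219 genes (induced 3 and 4) were shared, at correlations of 0.90 and 0.77. Induced 1 to 3 shared a slide and were alike (median differences 0.05 to 0.07), so these pairs were not independent. The largest shared rises were BDKRB1, a kinin receptor (3.50 against uninduced and 3.37 against shControl), MCAM, a cell adhesion molecule (3.11 and 2.58), KIF13B, a kinesin (3.08 and 2.72), C19orf33 (3.07 and 3.28), SERPINA5 (2.73 and 2.86) and FAAH2 (2.67 and 2.56). The largest shared falls, next to TACC3 itself, were PIGF, which acts in GPI anchor synthesis (-3.15 and -3.41), STAG3, a meiotic cohesin subunit (-3.08 and -3.26), LAMP3 (-3.03 and -3.44), AP1S2 (-2.50 and -2.85) and NCAM2 (-2.50 and -2.74).

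Of 40 genes of mitosis and G2/M, 37 fell and 0 rose against uninduced cells (median -0.68, camera adjusted p = 5.41e-13, and adjusted p = 0.0846 with an estimated correlation). Against shControl 38 fell and 0 rose (median -0.80, adjusted p = 7.42e-14, and adjusted p = 0.0769 with an estimated correlation). Examples were CENPF, a kinetochore protein (-1.44 and -1.69), KIF11, a spindle kinesin (-1.39 and -1.54), and the proliferation marker MKI67 (-1.51 ± 0.15, adjusted p = 7.87e-06, and -1.73 ± 0.15, adjusted p = 2.21e-06). Of 38 DNA replication and S phase genes 29 fell and 0 rose against uninduced cells (median -0.64, adjusted p = 2.33e-10, and adjusted p = 0.0418 with an estimated correlation). Against shControl 33 fell and 0 rose (median -0.63, adjusted p = 1.06e-10, and adjusted p = 0.0501 with an estimated correlation). E2F1, a transcription factor of S phase entry, stood at 0.46 ± 0.07 in induced cells, 2.61 ± 0.11 in uninduced and 2.82 ± 0.08 in shControl cells (SD, n = 4 each), a fall of 2.15 and 2.36. Histone genes rose in 13 of 17 cases and fell in 2 against either control, with medians of 1.45 (adjusted p = 1.77e-06, and adjusted p = 0.0418 with an estimated correlation) and 1.98 (adjusted p = 4.08e-06, and adjusted p = 0.0501 with an estimated correlation). H2AC8 rose by 2.42 and 2.62. Of 21 cholesterol synthesis genes 12 rose and 1 fell against uninduced cells (median 0.27, adjusted p = 0.00524, and adjusted p = 0.0538 with an estimated correlation). Against shControl 13 rose and 2 fell (median 0.28, adjusted p = 0.0193, and adjusted p = 0.0769 with an estimated correlation), although with spike-in scaling that median was -0.05 (adjusted p = 0.389). This call was also lost with median scaling (0.13, adjusted p = 0.113) and in the first scan session alone (adjusted p = 0.102), and against uninduced cells with spike-in scaling (adjusted p = 0.0546).

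Among 31 p53 targets, 12 rose and 5 fell against uninduced cells (median 0.24, adjusted p = 0.139) and 11 rose and 6 fell against shControl (median 0.15, adjusted p = 0.360). MDM2, the p53 ubiquitin ligase, measured -0.32 ± 0.18 (adjusted p = 0.169) and 0.22 ± 0.18 (adjusted p = 0.342). Of 7 sirtuins 3 rose against uninduced cells (median 0.14, adjusted p = 0.406), and 4 rose and 1 fell against shControl (median 0.29, adjusted p = 0.360). Beside SIRT4, SIRT6 rose by 0.31 (adjusted p = 0.00468) and 0.55 (adjusted p = 8.60e-05), and SIRT3 by 0.27 (adjusted p = 0.0125, but -0.01 as the mean of its probes) and 0.29 (adjusted p = 0.00669, but -0.04 with spike-in scaling). SIRT3 lost its call on slide 2 (0.17, adjusted p = 0.155) and slide 3 (0.19, adjusted p = 0.167), and against shControl on slide 3 (0.24, adjusted p = 0.0896). SIRT2 measured 0.15 (adjusted p = 0.238) and rose by 0.30 against shControl (adjusted p = 0.0196, but -0.03 with spike-in scaling), and SIRT5 measured -0.31 (adjusted p = 0.0814) and fell by 0.46 (adjusted p = 0.0132). Its 3 probes differed in direction. SIRT1 measured 0.04 and 0.03, and SIRT7 -0.01 and -0.07. Oxidative phosphorylation genes rose in 14 and fell in 2 of 34 cases against uninduced cells (median 0.21, adjusted p = 0.0638) and in 11 and 3 against shControl (median 0.17, adjusted p = 0.354). Lysosomal genes rose in 13 and fell in 3 of 27 cases (median 0.19, adjusted p = 0.116) and in 11 and 5 (median 0.11, adjusted p = 0.427). Antioxidant and NRF2 targets rose in 9 and fell in 8 of 25 cases (median 0.15, adjusted p = 0.876) and in 10 and 8 (median 0.12, adjusted p = 0.731).

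Secretory factors of senescence rose in 2 and fell in 2 of 11 cases against uninduced cells (median 0.06, adjusted p = 0.993) and in 5 and 2 against shControl (median 0.33, adjusted p = 0.427). Telomere, nuclear envelope and senescence markers rose in 3 and fell in 4 of 13 cases (median -0.25, adjusted p = 0.876), then 4 and 6 against shControl (median 0.04, mean -0.12, test downward, adjusted p = 0.731). LMNB1, the nuclear lamin B1, fell by 1.02 ± 0.29 (adjusted p = 0.0121) and 0.74 ± 0.29 (adjusted p = 0.0485, with arrays of the groups overlapping), and LMNB2 by 0.97 and 0.99. Leaving out any array but shControl 1 ended the call of LMNB1 against shControl (-0.77 to -0.60, and -1.14 without shControl 1). Estrogen receptor targets rose in 5 and fell in 6 of 23 cases (median 0.02, mean -0.06, test downward, adjusted p = 0.876), then 10 and 7 (median 0.07, mean -0.02, test upward, adjusted p = 0.731). Luminal identity genes rose in 3 and fell in 4 of 15 cases (median -0.07, adjusted p = 0.876), then 2 and 5 (median -0.08, adjusted p = 0.584). Interferon-stimulated genes rose in 6 and fell in 8 of 26 cases (median -0.05, adjusted p = 0.866), then 9 and 3 (median 0.07, adjusted p = 0.354). ATF4 and unfolded protein response genes rose in 7 and fell in 5 of 22 cases (median 0.12, adjusted p = 0.725), then 5 and 8 (median -0.07, adjusted p = 0.584). Reported targets of miR-15/16 rose in 6 and fell in 2 of 16 cases (median -0.00, mean 0.20, test upward, adjusted p = 0.463), then 4 and 3 (median 0.07, adjusted p = 0.427). Markers of other cell types gave 0 calls of 3 for fibroblasts (medians -0.25 and -0.08, adjusted p = 0.876 and 0.782) and 0 of 6 for leukocytes (medians 0.04 and 0.35, adjusted p = 0.993 and 0.644). Basal and mesenchymal markers rose in 1 and fell in 4 of 7 cases (median -0.68, adjusted p = 0.435), then 2 and 4 (median -0.83, adjusted p = 0.427).

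Adjusted over the list alone, counts against uninduced cells became 0 up and 30 down for replication, 9 and 9 for NRF2 targets, 2 and 6 for estrogen receptor targets and 6 and 9 for interferon-stimulated genes. Against shControl they became 0 and 34 for replication, 1 and 5 for luminal identity and 14 and 2 for cholesterol synthesis, and every other count stayed. With the slide as a block limma called 7498 genes against uninduced cells and 7397 against shControl. Against uninduced cells it called 7618 on slide 2 alone and 6170 on slide 3 alone, where 99.97% and 99.6% of the main calls kept their sign, and against shControl 7372 on slide 3 (98.9%). The main calls were made on these same arrays, so the agreement of sign was nearly given in advance. Slide 2 held 1 uninduced array, and slide 3 held 1 uninduced and 1 induced array, so the spread there came from the other arrays alone. All 4 called lists kept their direction and call in each of these, with medians within 0.11 of the pooled ones, at -0.71 and -0.68 for mitosis and 1.44 and 1.34 for histones on slides 2 and 3. TACC3 measured -3.39 on slide 2 and -3.46 on slide 3 against uninduced cells and -3.68 on slide 3 against shControl, and SIRT4 1.77, 1.75 and 2.11. Spike-in scaling lowered the calls to 339 and 963 (166 up and 797 down against shControl, where the median change of all genes moved by -0.33), and median scaling moved it by -0.15 against shControl (1597 up, 3256 down). With spike-in scaling and the scan session as a block limma called 7372 and 7601 genes. The median change of all genes then moved by 0.04 and -0.10. All main calls, SIRT2 and SIRT3 included, then kept their sign, but they were made on the same arrays.

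**Figure D2:**
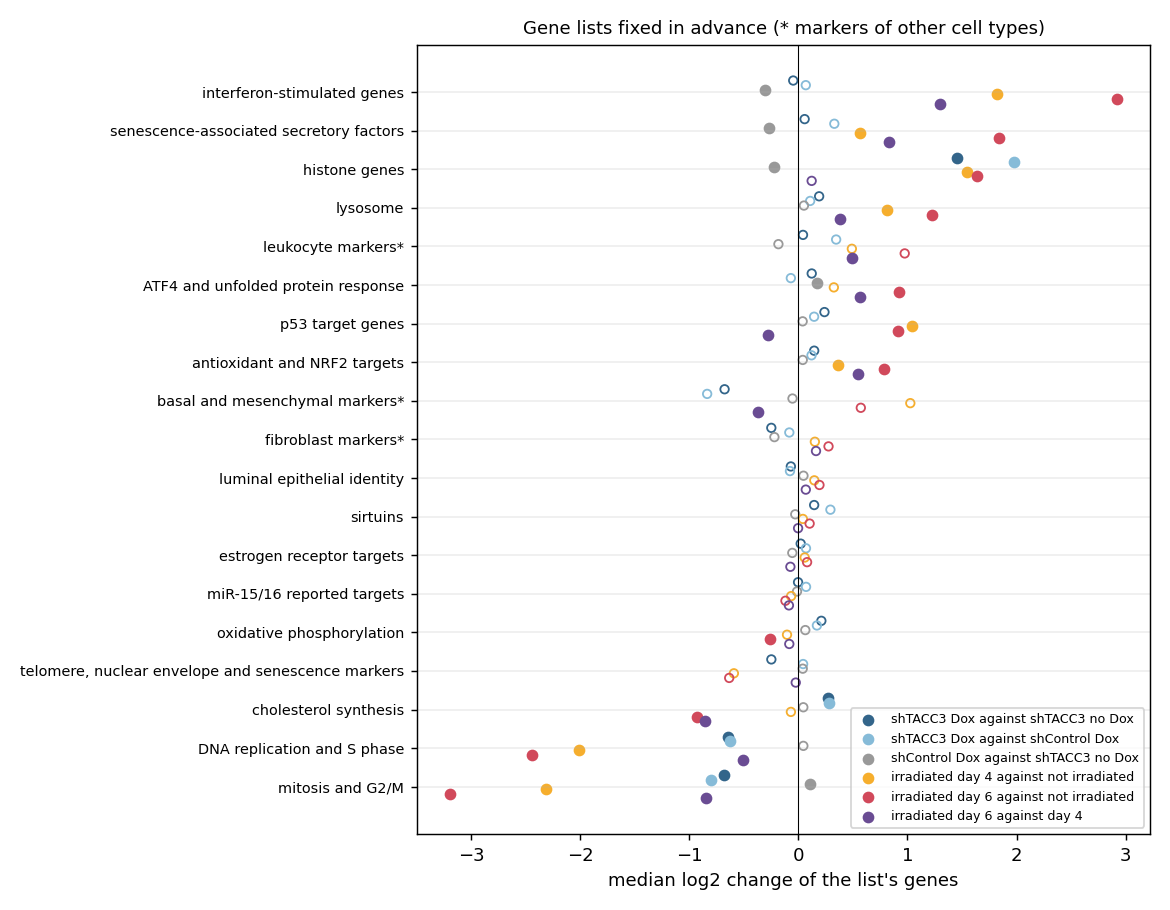
Median log2 change of each mRNA list in each comparison. Filled dots passed the camera test at an adjusted p of 0.05 with the preset correlation, open dots did not. An asterisk marks lists of markers of other cell types.

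In the shControl cells with doxycycline, set against uninduced shTACC3 cells, interferon-stimulated genes, histone genes and secretory factors were lower and ATF4 and unfolded protein response genes higher. With an estimated correlation each of these calls was lost, and that of secretory factors also with the slide as a block. TACC3 measured 0.08 ± 0.09 (adjusted p = 0.670) and SIRT4 -0.32 ± 0.14 (adjusted p = 0.235), while CDKN1A fell by 0.36 ± 0.06 (adjusted p = 0.00353, n = 4 each). That call was lost on slide 1 alone (-0.31, adjusted p = 0.472) and slide 3 alone (-0.40, adjusted p = 0.127), and with spike-in scaling CDKN1A measured 0.02 (adjusted p = 0.976). The largest rises were MAOB, a monoamine oxidase (2.58), SLC24A3 (2.42), the nuclear receptor NR4A2 (2.19), GULP1 (1.99), DDC (1.93) and NT5E (at least 1.81, with all uninduced arrays at the floor). The largest falls were S100A8, a calcium-binding protein of inflammation (-3.24, adjusted p = 1.04e-06), LCN2, an iron-carrier protein (at least 4.81-fold lower, above background on 0 of 4 shControl arrays, adjusted p = 0.00617), AOX1 (-1.91), SERPINA3 (-1.88), FST (-1.71) and SERPINA1 (-1.54). limma called 980 genes (520 up, 460 down), 29 and 31 of them at least 2-fold.

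Of 26 interferon-stimulated genes 9 fell and 0 rose (median -0.30, adjusted p = 2.07e-07, and adjusted p = 0.0628 with an estimated correlation). Of 22 ATF4 and unfolded protein response genes 4 rose and 0 fell (median 0.17, adjusted p = 6.15e-04, and adjusted p = 0.0544 with an estimated correlation). Histone genes fell in 6 of 17 cases and rose in 0 (median -0.22, adjusted p = 0.00971, and adjusted p = 0.214 with an estimated correlation), and the call was also lost with median scaling (-0.07, adjusted p = 0.0643). Secretory factors fell in 3 of 11 cases and rose in 0 (median -0.27, adjusted p = 0.0343, and adjusted p = 0.145 with an estimated correlation). Mitosis genes had a median of 0.11 (adjusted p = 0.0114, and adjusted p = 0.602 with an estimated correlation), although 0 of 40 rose and only MELK fell (-0.39). With spike-in scaling the medians of interferon-stimulated genes, histones and secretory factors turned positive (0.07, 0.16 and 0.11). With the scan session as a block besides they were -0.17, -0.09 and 0.05, and all but secretory factors kept direction and call.

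The remaining lists did not pass. p53 targets rose in 1 and fell in 2 of 31 cases (median 0.04, adjusted p = 0.470), replication genes in 0 and 0 of 38 (median 0.05, adjusted p = 0.258), sirtuins in 0 and 0 of 7 (median -0.03, adjusted p = 0.465) and oxidative phosphorylation genes in 0 and 0 of 34 (median 0.06, adjusted p = 0.291). NRF2 targets rose in 1 and fell in 2 of 25 cases (median 0.04, mean -0.02, test upward, adjusted p = 0.614). Estrogen receptor targets rose in 3 and fell in 3 of 23 (median -0.05, adjusted p = 0.438), luminal genes in 1 and 0 of 15 (median 0.05, adjusted p = 0.470), lysosomal genes in 0 and 0 of 27 (median 0.05, adjusted p = 0.148) and cholesterol genes in 0 and 0 of 21 (median 0.05, adjusted p = 0.520). Targets of miR-15/16 rose in 1 and fell in 1 of 16 (median -0.01, mean 0.02, test upward, adjusted p = 0.767). Senescence markers rose in 0 and fell in 3 of 13 (median 0.04, mean -0.03, test downward, adjusted p = 0.711). Fibroblast markers gave 0 calls of 3 (median -0.22, mean 0.14, test downward, adjusted p = 0.767), leukocyte markers 0 of 6 (median -0.18, adjusted p = 0.406), and basal markers 1 up and 1 down of 7 (median -0.05, adjusted p = 0.852).

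Adjusted over the list alone, counts in this comparison became 1 up and 14 down for interferon-stimulated genes, 5 and 0 for ATF4 genes, 1 and 7 for histones, 1 and 4 for secretory factors, 3 and 5 for estrogen receptor targets, 1 and 3 for senescence markers and 2 and 1 for basal markers. With the slide as a block limma called 2161 genes, and within slide 1 and within slide 3 (1 uninduced array) it called 0 (1424 and 3923 genes at a raw p below 0.05), though all 980 kept their sign in both. The list medians with the slide as a block, on slide 1 and on slide 3 were -0.29, -0.28 and -0.39 for interferon-stimulated genes, 0.14, 0.21 and 0.09 for ATF4 genes, -0.22, -0.06 and -0.32 for histones, 0.08, 0.11 and 0.06 for mitosis, and -0.06, -0.09 and -0.14 for secretory factors. The call was lost with the block for secretory factors (adjusted p = 0.114), on slide 1 for mitosis (0.137), secretory factors (0.143) and histones (0.313), and on slide 3 for secretory factors (0.351). The median change of all genes moved by 0.15 with median scaling (201 up, 58 down), by 0.38 with spike-in scaling (9 up, 1 down) and by 0.12 with spike-in scaling and the scan session as a block (2243 up, 298 down).

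Among miRNAs, miR-15b and members of miR-17~92 and its paralogs were lower with TACC3 shRNA and doxycycline, while miR-15a and miR-16 showed no change past the threshold with this scaling. miR-15b had a scaled log2 signal of 2.81 ± 0.04 (SD, n = 3) in induced cells, 3.46 ± 0.15 (n = 3) in uninduced cells and 3.46 on the 1 shControl array. It fell by 0.65 ± 0.08 (SE) against uninduced cells (adjusted p = 0.00888, 1.56-fold), a call lost with quantile normalization, no filter, the replicate block and series matrix values. It fell by 0.65 ± 0.12 against the shControl array (adjusted p = 0.0350, from the spread of the other groups, since 1 array has none). That call was lost without any 1 induced array, and quantile normalization gave -0.23. miR-15a measured 0.00 (adjusted p = 1) and 0.01, and miR-16 -0.11 (adjusted p = 0.540) and -0.21 (adjusted p = 0.397). Against uninduced cells without scaling between arrays, where induced arrays were dimmer, miR-15a measured -0.47 (adjusted p = 0.0220) and miR-16 -0.58, also past the threshold, as was miR-16 with quantile normalization (-0.15).

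limma called 66 of 231 miRNAs against uninduced cells (33 up, 33 down, with 1 and 1 at least 2-fold) and 40 against the shControl array (20 up, 20 down, with 1 and 0 at least 2-fold). Leaving out 1 array gave 32 to 68 against uninduced cells, and leaving out 1 induced array gave 1 to 20 against shControl. Of 12 members of miR-17~92 and its paralogs, which cell-cycle transcription factors are known to control, 10 fell and 0 rose against uninduced cells (median -0.60, adjusted p = 4.53e-06, and adjusted p = 0.702 with an estimated correlation). Against shControl 5 fell and 0 rose (median -0.61, adjusted p = 7.08e-04, and adjusted p = 0.731 with an estimated correlation). miR-18a fell by 1.20 ± 0.10 (adjusted p = 0.00631) and 0.94 (adjusted p = 0.0292), and miR-17 by 0.90 ± 0.12 (adjusted p = 0.00985) and 0.93. Of 7 members of the miR-15/16 family 2 fell and 0 rose against uninduced cells (median -0.11, adjusted p = 0.0423, and adjusted p = 0.702 with an estimated correlation). Against shControl 4 fell and 0 rose (median -0.42, adjusted p = 0.00114, and adjusted p = 0.664 with an estimated correlation). miR-503 fell by 0.37 ± 0.04 (adjusted p = 0.00631, but 0.05 with normexp correction) and 0.44 (adjusted p = 0.0207), miR-195 measured -0.11 (adjusted p = 0.102) and fell by 0.44 (adjusted p = 0.0220), and miR-424 measured -0.16 (adjusted p = 0.258) and -0.42 (adjusted p = 0.0883). miR-497, at the floor on the induced arrays, measured -0.07 (adjusted p = 0.286) and -0.31 (adjusted p = 0.0350, but 0.06 with normexp correction).

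The largest miRNA rises against uninduced cells were miR-181a* (1.05 ± 0.11, adjusted p = 0.00650), miR-181a (0.90, adjusted p = 0.0233), miR-21* (0.77), miR-1274a (0.70, adjusted p = 0.0171) and miR-1974 (0.69, adjusted p = 0.0364), and miR-7 fell by 0.84 (adjusted p = 0.0200). Against the shControl array they were miR-22 (1.13 ± 0.09, adjusted p = 0.0108), miR-21* (0.98), miR-181a* (0.97) and miR-1274a (0.91). Of 11 senescence-linked miRNAs 5 rose and 0 fell against uninduced cells (median 0.03, adjusted p = 0.0539), and 3 rose and 0 fell against shControl (median 0.06, adjusted p = 0.0571). miR-22 rose by 0.63 (adjusted p = 0.00631), miR-21 by 0.50 (adjusted p = 0.0179) and 0.60 (adjusted p = 0.0400), and miR-29a by 0.25 against shControl (adjusted p = 0.0372, but -0.19 with the percentile taken over all probes). Of 5 p53-induced miRNAs 0 rose and 1 fell in each comparison (median 0.04, adjusted p = 0.923, then median 0.05, mean -0.02, test downward, adjusted p = 0.791), namely miR-192 at -0.40 (adjusted p = 0.00706) and -0.30 (adjusted p = 0.0472), beside miR-34a at 0.38 ± 0.14 (adjusted p = 0.123) and 0.05. let-7 gave 0 calls of 9 in each (medians 0.16 and -0.12, adjusted p = 0.753 and 0.556). The miR-200 and epithelial group rose in 1 and fell in 1 of 6 cases (median 0.01, adjusted p = 0.923, miR-200a 0.52 and miR-429 -0.45), then 0 and 1 (median -0.12, adjusted p = 0.345, miR-205 -0.17, at the floor on all but the shControl array, so without a spread). 0 miRNAs of the leukocyte and fibroblast list were measured. Adjusted over the list alone, counts against shControl became 0 up and 5 down for the miR-15/16 family and 0 and 6 for miR-17~92, and all others stayed.

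Induced arrays and uninduced 3 lay on slide row 2 and the others on row 1, so the row block rests on uninduced 3 alone. With it limma called 66 miRNAs (42 of them shared with the main calls) and 39. miR-17~92 then had medians of -0.71 and -0.75, and the miR-15/16 family -0.16 and -0.44, losing its call against uninduced cells (adjusted p = 0.0623). With the percentile taken over all probes limma called 0 miRNAs in either comparison (24 and 23 at a raw p below 0.05) and gave miR-15b -0.87 (adjusted p = 0.478) and -1.09 (adjusted p = 0.435), and the comparison with shControl rested on 1 control array.

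**Figure D3:**
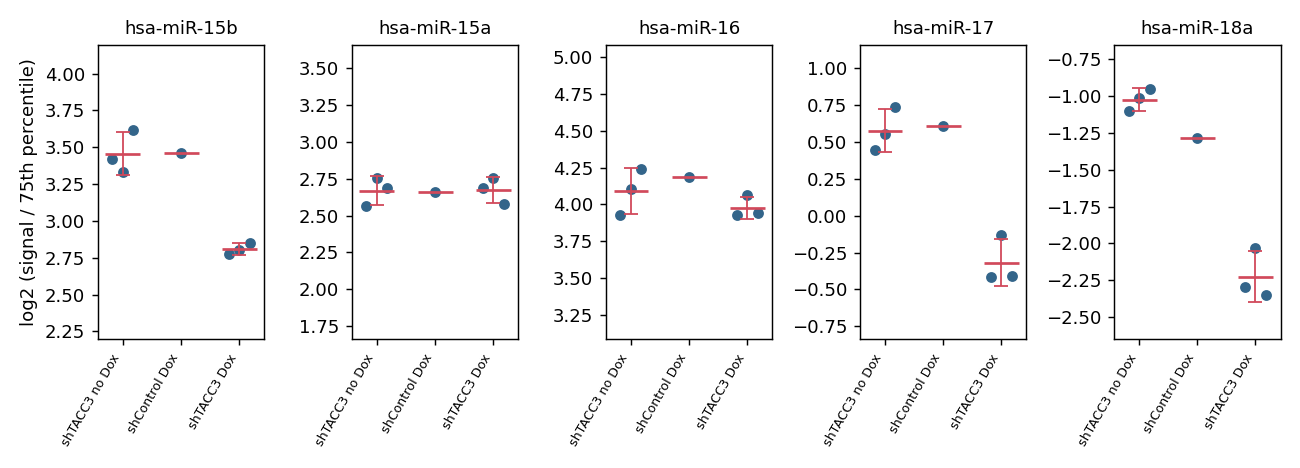
Scaled log2 signal of 5 miRNAs on every miRNA array. Each dot is 1 array, the wide bar the group mean and the whiskers the SD, and each panel spans 2 log2 units. The shControl group held 1 array and has no SD.

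At day 4 after 20 Gy, interferon-stimulated genes, p53 targets, lysosomal genes, histones, secretory factors and NRF2 targets were higher, and genes of mitosis and replication lower, than in cells that were not irradiated. With an estimated correlation the list calls were lost for interferon-stimulated genes, lysosome, histones, secretory factors and NRF2 targets. CDKN1A stood at 1.01 ± 0.04 (SD, n = 2) without irradiation and 4.54 ± 0.04 (n = 3) at day 4, a rise of 3.53 ± 0.05 (SE, adjusted p = 5.72e-08, 11.5-fold). TACC3 went from 1.14 ± 0.11 to -1.09 ± 0.08, a fall of 2.22 ± 0.07 (adjusted p = 4.08e-07, 4.67-fold), and SIRT4 from -4.60 ± 0.14 to -3.15 ± 0.01, a rise of 1.44 ± 0.07 (adjusted p = 2.73e-06, 2.72-fold). The largest rises were BCAS1 (4.96), XG (4.73), CST6, a cysteine protease inhibitor (4.64), IFIT1 (4.46), OAS1 (at least 4.30, with 1 array at the floor) and VTCN1, an immune checkpoint ligand (4.28). The largest falls included TDRD10 (-3.63), the linker histone H1-5 (-3.58 or lower, with 2 arrays at the floor), CDCA7 (-3.35), LMNB1 (-3.16 ± 0.32, adjusted p = 9.68e-05), the helicase PIF1 (-3.07) and H4C13 (-3.02).

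limma called 8909 of 14335 genes at day 4 (4649 up, 4260 down), 1279 and 836 of them at least 2-fold. All 40 mitosis genes fell (median -2.31, adjusted p = 2.49e-21, and adjusted p = 0.0138 with an estimated correlation). MKI67 changed by -2.12 ± 0.14 (adjusted p = 1.15e-05). Replication genes fell in 37 and rose in 1 of 38 cases (median -2.01, adjusted p = 6.59e-18, and adjusted p = 0.0249 with an estimated correlation). p53 targets rose in 28 and fell in 0 of 31 cases (median 1.04, adjusted p = 4.93e-11, and adjusted p = 0.0107 with an estimated correlation). MDM2 changed by 1.15 ± 0.09 (adjusted p = 2.60e-05). Interferon-stimulated genes rose in 29 and fell in 0 of 31 cases (median 1.82, adjusted p = 4.93e-11, and adjusted p = 0.181 with an estimated correlation). Lysosomal genes rose in 26 and fell in 0 of 27 cases (median 0.81, adjusted p = 4.99e-08, and adjusted p = 0.0625 with an estimated correlation). Histones rose in 13 and fell in 4 of 17 cases (median 1.55, adjusted p = 0.00146, and adjusted p = 0.198 with an estimated correlation). H2AC8 changed by 2.92. NRF2 targets rose in 19 and fell in 3 of 26 cases (median 0.37, adjusted p = 0.00188, and adjusted p = 0.123 with an estimated correlation), and with spike-in scaling 6 rose and 4 fell (median 0.04). Secretory factors rose in 13 and fell in 1 of 19 cases (median 0.57, adjusted p = 0.00258, and adjusted p = 0.0721 with an estimated correlation), and with spike-in scaling 9 rose and 3 fell (median 0.24).

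Sirtuins rose in 3 and fell in 2 of 7 cases at day 4 (median 0.04, adjusted p = 0.793). SIRT6 rose by 0.39 (adjusted p = 2.77e-04) and SIRT7 by 0.30 (adjusted p = 0.00406, but -0.03 with spike-in scaling), SIRT1 fell by 0.87 (adjusted p = 1.10e-04) and SIRT5 by 0.35 (adjusted p = 0.00384, but 0.16 as the mean of its probes), and SIRT2 and SIRT3 measured 0.04 and -0.19. Estrogen receptor targets rose in 9 and fell in 7 of 23 cases (median 0.06, mean -0.04, test downward, adjusted p = 0.785). Oxidative phosphorylation genes rose in 7 and fell in 12 of 34 (median -0.10, adjusted p = 0.245), ATF4 genes in 12 and 6 of 22 (median 0.33, adjusted p = 0.245) and cholesterol genes in 8 and 9 of 21 (median -0.07, adjusted p = 0.686). With spike-in scaling the counts were 0 up and 20 down (median -0.43) for oxidative phosphorylation, 5 and 7 (-0.08) for ATF4 genes, 2 and 11 (-0.40) for cholesterol, 3 and 9 (-0.27) for estrogen receptor targets, 3 and 4 (-0.18) for luminal genes and 2 and 9 (-0.40) for miR-15/16 targets. Luminal genes rose in 5 and fell in 1 of 15 cases (median 0.15, adjusted p = 0.269). Targets of miR-15/16 rose in 5 and fell in 6 of 16 (median -0.07, adjusted p = 0.471). Senescence markers rose in 4 and fell in 9 of 14 (median -0.59, adjusted p = 0.129). Markers of other cell types rose in 1 and fell in 0 of 5 for fibroblasts (median 0.15, adjusted p = 0.509), in 3 and 0 of 6 for leukocytes (median 0.49, adjusted p = 0.244) and in 5 and 1 of 8 for basal cells (median 1.03, adjusted p = 0.106). Adjusted over the list alone, counts became 29 up and 0 down for p53 targets, 3 and 3 for sirtuins, 8 and 10 for cholesterol synthesis and 5 and 7 for miR-15/16 targets, and all others stayed. With the slide as a block limma called 9136 genes, and 7476 on slide 1 and 8077 on slide 2, with all 8 lists called in each and medians within 0.14 of the pooled ones. Each slide held 1 non-irradiated array and slide 2 held 1 of day 4, so the spread came from the other arrays. Spike-in scaling moved the median change of all genes by -0.33 (2060 up, 5868 down).

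At day 6 the rises of interferon-stimulated genes, NRF2 targets and secretory factors were joined by a rise of ATF4 and unfolded protein response genes and by a fall of cholesterol synthesis genes. With an estimated correlation the list calls were lost for interferon-stimulated genes and ATF4 genes. CDKN1A stood at 4.51 ± 0.04 (SD, n = 3), 3.51 ± 0.05 (SE) above cells that were not irradiated (adjusted p = 1.41e-08, 11.4-fold). TACC3 stood at -1.95 ± 0.06, a fall of 3.08 ± 0.07 (adjusted p = 5.27e-08, 8.48-fold), and SIRT4 at -2.51 ± 0.07, a rise of 2.09 ± 0.07 (adjusted p = 2.87e-07, 4.26-fold). The largest rises were IFI27 (8.01), CYP1A1, a cytochrome P450 of the aryl hydrocarbon response (7.22), IFI6 (7.21), IFITM1 (7.11), complement factor CFB (6.80) and IFIT1 (6.47). The largest falls were LMNB1 (-4.44 ± 0.32, adjusted p = 1.15e-05), CCNA2 (-4.28), KIF18B (-4.20), CDCA7 (-4.13), PDZK1 (-4.07) and PIF1 (-3.96).

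limma called 10342 genes at day 6 (5706 up, 4636 down), 2014 and 1205 of them at least 2-fold. All 40 mitosis genes fell (median -3.19, adjusted p = 5.46e-21, and adjusted p = 0.0194 with an estimated correlation). MKI67 changed by -3.20 ± 0.14 (adjusted p = 9.79e-07). Replication genes fell in 37 and rose in 1 of 38 cases (median -2.44, adjusted p = 2.60e-17, and adjusted p = 0.0194 with an estimated correlation). Interferon-stimulated genes rose in 30 and fell in 0 of 31 cases (median 2.92, adjusted p = 2.07e-11, and adjusted p = 0.131 with an estimated correlation). Lysosomal genes rose in 26 and fell in 0 of 27 cases (median 1.23, adjusted p = 1.87e-07, and adjusted p = 0.0407 with an estimated correlation). NRF2 targets rose in 22 and fell in 2 of 26 cases (median 0.78, adjusted p = 1.38e-05, and adjusted p = 0.0407 with an estimated correlation), led by the aldo-keto reductase AKR1C3 (6.35), and with spike-in scaling 11 rose and 3 fell (median 0.15). Secretory factors rose in 17 and fell in 1 of 19 cases (median 1.84, adjusted p = 1.38e-05, and adjusted p = 0.0194 with an estimated correlation). p53 targets rose in 22 and fell in 3 of 31 cases (median 0.91, adjusted p = 7.39e-05, and adjusted p = 0.0194 with an estimated correlation), and with spike-in scaling 14 rose and 10 fell (median 0.28). MDM2 changed by 1.16 ± 0.09 (adjusted p = 1.72e-05). ATF4 and unfolded protein response genes rose in 18 and fell in 3 of 22 cases (median 0.92, adjusted p = 0.00101, and adjusted p = 0.0807 with an estimated correlation), and with spike-in scaling 7 rose and 5 fell (median 0.09). DDIT3, the factor CHOP, changed by 3.27. Histones rose in 13 and fell in 4 of 17 cases (median 1.64, adjusted p = 0.00366, and adjusted p = 0.218 with an estimated correlation).

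Cholesterol synthesis genes fell in 18 and rose in 3 of 21 cases at day 6 (median -0.92, adjusted p = 1.64e-05, and adjusted p = 0.0194 with an estimated correlation). Oxidative phosphorylation genes fell in 16 and rose in 6 of 34 cases (median -0.26, adjusted p = 0.0353, and adjusted p = 0.558 with an estimated correlation), and with spike-in scaling 29 fell and 1 rose (median -0.89). Sirtuins rose in 3 and fell in 3 of 7 cases (median 0.10, adjusted p = 0.907): SIRT6 rose by 0.39 (adjusted p = 2.22e-04, but -0.24 with spike-in scaling) and SIRT2 by 0.26 (adjusted p = 0.00331, but -0.04 with median and -0.38 with spike-in scaling). SIRT1 fell by 1.00 (adjusted p = 3.91e-05), SIRT3 by 0.36 (adjusted p = 0.00338) and SIRT5 by 0.34 (adjusted p = 0.00374, but 0.20 as the mean of its probes), and SIRT7 measured 0.10 (adjusted p = 0.170). Estrogen receptor targets rose in 11 and fell in 9 of 23 cases (median 0.08, mean -0.18, test downward, adjusted p = 0.664). Luminal genes rose in 7 and fell in 3 of 15 cases (median 0.19, adjusted p = 0.337). Targets of miR-15/16 rose in 7 and fell in 8 of 16 (median -0.12, adjusted p = 0.381). Senescence markers rose in 6 and fell in 8 of 14 (median -0.63, adjusted p = 0.293). Markers of other cell types rose in 2 and fell in 0 of 5 for fibroblasts (median 0.28, adjusted p = 0.337), in 6 and 0 of 6 for leukocytes (median 0.98, adjusted p = 0.0528) and in 4 and 1 of 8 for basal cells (median 0.57, adjusted p = 0.296). With spike-in scaling the counts were 4 up and 13 down (median -0.55) for estrogen receptor targets, 2 and 8 (-0.44) for luminal genes and 2 and 9 (-0.75) for miR-15/16 targets. Adjusted over the list alone, counts became 23 up and 3 down for p53 targets and 6 and 1 for basal markers, and all others stayed.

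With the slide as a block limma called 10592 genes at day 6, and 8876 on slide 1 (1 array of each group compared) and 9887 on slide 2 (1 non-irradiated array), with the spread from the other arrays. All 11 called lists kept direction and call, with medians within 0.23 of the pooled ones, except oxidative phosphorylation on slide 2 (-0.11, adjusted p = 0.108), and the leukocyte markers passed with the block (0.97, adjusted p = 0.0296). The median change of all genes moved by -0.28 with median scaling (3832 up, 6353 down), by -0.63 with spike-in scaling (1969 up, 8244 down) and by 0.12 with normexp correction (5909 up, 3613 down). Days 4 and 6 share their non-irradiated arrays: 4087 genes rose at both (1851 expected if independent) and 3756 fell at both (1378 expected), and the changes correlated at 0.90 with a covariance of 0.73, against 0.60 and 0.01 in simulated data without effect, which gave 0 shared calls.

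From day 4 to day 6, interferon-stimulated genes, NRF2 targets, ATF4 genes and secretory factors rose further, mitosis and replication genes fell further, and cholesterol synthesis genes and p53 targets fell. The list call of interferon-stimulated genes was lost with an estimated correlation. TACC3 fell by a further 0.86 ± 0.06 (SE, adjusted p = 7.72e-05, n = 3 each) and SIRT4 rose by a further 0.65 ± 0.06 (adjusted p = 2.66e-04, 1.57-fold), while CDKN1A measured -0.02 (adjusted p = 0.696). The largest rises were IFI27 (4.82), the secreted phospholipase PLA2G2F (4.53), LGI2 (4.34), IGKV2-24 (4.20), IFI6 (4.04) and CCKBR (at least 3.98, with 1 array of day 4 at the floor). The largest falls were NT5E (-2.74), PDZK1 (-2.61), the Wnt inhibitor DKK1 (-2.55), SLC26A2 (-2.30), EFEMP1 (-2.26) and PEG10 (-2.22). limma called 6777 genes (3645 up, 3132 down), 423 and 120 of them at least 2-fold.

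Mitosis genes fell in all 40 cases from day 4 to day 6 (median -0.84, adjusted p = 6.44e-21, and adjusted p = 0.0138 with an estimated correlation). MKI67 changed by -1.08 ± 0.13 (adjusted p = 5.50e-04, but 0.13 with normexp correction). Replication genes fell in 33 and rose in 1 of 38 (median -0.51, adjusted p = 5.92e-13, and adjusted p = 0.0259 with an estimated correlation). Cholesterol genes fell in 20 and rose in 0 of 21 (median -0.85, adjusted p = 5.92e-13, and adjusted p = 0.00826 with an estimated correlation). Interferon-stimulated genes rose in 25 and fell in 3 of 31 (median 1.30, adjusted p = 3.80e-10, and adjusted p = 0.144 with an estimated correlation). NRF2 targets rose in 20 and fell in 0 of 26 (median 0.54, adjusted p = 5.72e-09, and adjusted p = 0.0203 with an estimated correlation), and with spike-in scaling 12 rose and 1 fell (median 0.24). Secretory factors rose in 16 and fell in 1 of 19 (median 0.83, adjusted p = 1.03e-07, and adjusted p = 0.0138 with an estimated correlation). ATF4 genes rose in 18 and fell in 0 of 22 (median 0.57, adjusted p = 1.67e-07, and adjusted p = 0.0245 with an estimated correlation), and with spike-in scaling 9 rose and 1 fell (median 0.19). Lysosomal genes rose in 20 and fell in 0 of 27 (median 0.38, adjusted p = 2.31e-04, and adjusted p = 0.118 with an estimated correlation), but with spike-in scaling 1 rose and 4 fell (median 0.08). p53 targets fell in 15 and rose in 5 of 31 (median -0.28, adjusted p = 0.00294, and adjusted p = 0.0403 with an estimated correlation).

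Leukocyte markers rose in 3 and fell in 0 of 6 cases from day 4 to day 6 (median 0.49, adjusted p = 0.0470, and adjusted p = 0.258 with an estimated correlation). Basal markers fell in 5 and rose in 1 of 8 (median -0.37, adjusted p = 0.0470, and adjusted p = 0.144 with an estimated correlation). Sirtuins rose in 2 and fell in 1 of 7 (median -0.00, mean 0.05, test downward, adjusted p = 0.981). SIRT2 changed by 0.21 (adjusted p = 0.00874, but -0.09 with spike-in scaling) and SIRT7 by -0.20 (adjusted p = 0.0238). Histones rose in 7 and fell in 2 of 17 (median 0.12, adjusted p = 0.237), oxidative phosphorylation genes in 1 and 10 of 34 (median -0.08, adjusted p = 0.0511), estrogen receptor targets in 7 and 8 of 23 (median -0.07, adjusted p = 0.245) and luminal genes in 4 and 3 of 15 (median 0.07, adjusted p = 0.717). Targets of miR-15/16 rose in 3 and fell in 6 of 16 (median -0.09, adjusted p = 0.186), senescence markers in 4 and 5 of 14 (median -0.02, mean 0.06, test downward, adjusted p = 0.799, LMNB1 -1.28 ± 0.28) and fibroblast markers in 2 and 0 of 5 (median 0.16, adjusted p = 0.288). With spike-in scaling the counts were 1 up and 21 down (median -0.39) for oxidative phosphorylation, 1 and 5 (-0.18) for histones, 1 and 12 (-0.38) for estrogen receptor targets, 1 and 5 (-0.23) for luminal genes and 2 and 10 (-0.39) for miR-15/16 targets. Adjusted over the list alone, counts became 1 up and 34 down for replication, 18 and 1 for secretory factors, 21 and 0 for NRF2 targets, 4 and 4 for luminal genes, 20 and 1 for lysosome, 7 and 3 for histones and 5 and 5 for senescence markers, and all others stayed. With the slide as a block limma called 6746 genes, and 3441 on slide 1 (1 array of day 6) and 3094 on slide 2 (1 array of day 4), with the spread from the other arrays. The 11 lists kept their direction, with medians within 0.20 of the pooled ones, and the call was lost for basal markers in each (adjusted p = 0.0662, 0.0738 and 0.0892) and for leukocyte markers on slide 2 (0.0503). The median change of all genes moved by -0.17 with median scaling (1926 up, 5238 down) and by -0.30 with spike-in scaling (932 up, 5580 down), and normexp correction gave 4445 up and 1949 down.

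The genes changed by TACC3 shRNA with doxycycline overlapped with those changed by irradiation in the same direction. SIRT4, CDKN1A and H2AC8 rose and TACC3 and MKI67 fell in both experiments. Of the 13441 genes tested in both experiments, 1617 rose against both TACC3 controls and at day 4 (911 expected, Fisher p = 1.09e-213) and 1711 fell (937 expected, p = 4.38e-248), while 1013 went in opposite directions (1851 expected). On the later day 1673 rose (1072 expected, Fisher p = 4.13e-149), 1804 fell (1020 expected, p = 2.24e-247) and 1122 went in opposite directions (2101 expected). Across genes the changes correlated at 0.39 (against uninduced cells) and 0.40 (against shControl) with day 4, and at 0.38 and 0.42 with day 6, and these Fisher tests take genes as independent.

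**Figure D4:**
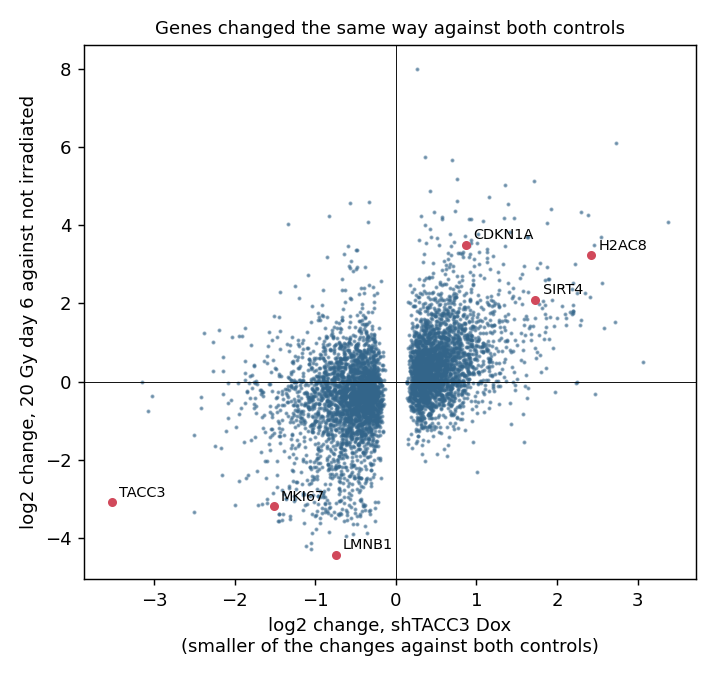
Genes called in the same direction against both TACC3 controls. The horizontal axis shows the smaller of the changes against both controls and the vertical axis the change at day 6 after 20 Gy. Named genes are marked in red.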

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

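The tests of the spike-in ratio, of spike-in scaling, of the scan session and of doxycycline were chosen after their results were seen, and the tests of dim probes and of other splits before. For array measures and named genes, each group of 4 arrays was searched for a value far from the other 3. The search used Dixon's ratio at its 95% critical value. Of 218 such sets of 4 values, 24 held an outlying value, where chance gives about 10.9. Many sets came from the same arrays and were not independent, so that expected count is only a rough guide. Induced array 4 stood apart in the share of probes detected (60.3%) and in the log2 ratio of its 75th percentile to the spike-ins (0.0444), and it was read in the second scan session. It also stood apart in DDB2 (2.48), GCLM (-0.66), GULP1 (-4.08), KCNK5 (-0.63), SERPINA1 (-3.50), SIRT2 (0.30), SIRT5 (0.00534) and STAG3 (-3.85). Uninduced array 4 stood apart in BDKRB1 (-4.06), DDB2 (3.38) and PHGDH (2.91), uninduced array 2 in CDKN1A (0.81) and LCN2 (-3.35), and induced array 1 in LCN2 (-3.13). shControl array 1 stood apart in LMNB1 (1.63), STC2 (2.36) and TACC3 (1.02), and shControl array 2 in DNAJB9 (1.12), GATA3 (3.85), PHGDH (3.06), SIRT7 (1.59) and UHRF1 (2.24).

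The change after irradiation differed between day 6 and day 4 in 6777 genes by the limma test of the difference. Of 8000 genes called on both days 7843 had the same direction, of which 3417 lay farther from the non-irradiated level at day 6 and 717 nearer. The other 157 were called in opposite directions (96 up at day 4 and down at day 6, 61 the other way), among them 5 cholesterol synthesis genes and 3 p53 targets. Probes without a gene symbol, used in no comparison above, changed the same way against both TACC3 controls in 1531 of 5867 cases (767 up, 764 down), and at day 6 in 3675 of 6482 cases (2178 up, 1497 down).

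The arrays of irradiated cells were dimmer against their spike-ins: the log2 ratio of the 75th percentile to the spike-ins was lower than without irradiation by 0.33 at day 4 and 0.63 at day 6 (difference -0.63, larger group SD 0.19). Dimmer hybridisation or scanning that lowers probes and spike-ins alike would leave that ratio unchanged, which argues against it as the whole explanation. Of 30 interferon-stimulated genes called up at day 6, 27 were also called up with spike-in scaling and 0 were called down, which speaks against rises of these genes made by the percentile scaling. Of 22 p53 targets called up at day 6, 14 were also called up with spike-in scaling and 2 were called down, so for these the scaling stays open as part of the rise. Less spike-in mix or more RNA in the reactions of the non-irradiated arrays cannot be told apart from a change in the cells, because the spike-in signal itself (difference -0.51, SD 0.17) also follows hybridisation and labelling. A lower content of mRNA in irradiated cells may stand behind the ratio and was not tested.

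The response to TACC3 shRNA with doxycycline was set against the scan session and against doxycycline itself. A fit of the first scan session alone called 5877 genes the same way against both controls, against 5753 with all arrays (5171 shared), which argues against the scan session and its extraction settings as the whole explanation. In that session shControl and induced arrays lay on different slides. The 6727 genes called in induced against uninduced cells were then followed in shControl cells with doxycycline against uninduced cells, which had no part in choosing them except for the shared uninduced arrays. Signed by their direction they had a median change of 0.00257 there (quartiles -0.12 and 0.11), against 0.52 in induced cells, with 319 called the same way and 369 the opposite way. Doxycycline alone would have moved them alike in both, so this argues against it as the whole explanation, although the cell lines also differ there. An effect of TACC3 loss may account for the response, and effects of this shRNA on other transcripts stay open, since 1 shRNA was used.

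The rise of SIRT4 rested on 1 dim probe, at 7.83% of the ranks of mean signal in the TACC3 experiment and 18.3% in the irradiation experiment. Among 1126 genes of like signal in the TACC3 experiment its change lay at the 98.1 percentile against uninduced cells and at 98.5 against shControl, which argues against a general offset of dim probes there. Among 1213 genes of like signal in the irradiation experiment it lay at the 89.3 percentile on the lower of both days, where 10.7% of such genes rose as much and the median change was 0.43, so an offset of dim probes stays open as part of that rise. A response of SIRT4 to irradiation could not be separated from it with this 1 probe.

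Other splits of the same arrays into groups of the same sizes were tested the same way. Against uninduced cells only the real split of 35 gave as many genes (6727, highest other 176). Same-numbered arrays shared a scan session there, so pairing was not shown. The 8 splits that part as many (highest other 0, at most 5 lists) are too few for a share under 0.05. The others keep some together. The gene lists past the threshold were matched by 14 of 35 splits (highest other 7). The medians of replication, mitosis, histones and cholesterol synthesis were each matched by 1 of 35, the real one (highest others 0.41, 0.44, 0.90 and 0.17). Against shControl 1 of 35 splits gave as many genes (highest other 0), 9 of 35 as many lists (highest other 5), and 1 of 35 as large a median for each of the same 4 lists (highest others 0.43, 0.50, 1.12 and 0.20). For genes changed against both controls 1 of 100 drawn splits, the real one, gave as many (highest other 2).

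For shControl against uninduced cells 2 of 35 splits gave as many genes, and the other one called 1358 against 980, so chance is not excluded. That split set shControl 1, 3 and 4 with uninduced 4 against the rest. It holds all of slide 3, as did the 2 others with any call (98 and 1), while 2 more that keep slide 3 together and all 29 that divide it gave 0. A part of slide and scan session in it stays open. As many lists came from 3 of 35 splits (highest other 5), as large a median for mitosis from 3 of 35 (highest other 0.16) and for secretory factors from 2 of 35 (highest other 0.28). For interferon-stimulated genes, histones and ATF4 genes it was 1 of 35 (highest others 0.19, 0.16 and 0.14), but these splits take no account of slide and scan session. The histone median was -0.06 on slide 1 (adjusted p = 0.313) and -0.07 in the first scan session (adjusted p = 0.315). With 3 against 3 arrays, 10 splits are too few for a share under 0.05: for day 6 against day 4 the real split alone (1 of 10) gave 6777 genes (highest other 0) and 11 lists (highest other 10). For miRNAs against uninduced cells 1 of 10 gave 66 miRNAs (highest other 0) and 8 of 10 gave 2 lists or more (highest other 3).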

How the results depend on the processing

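Tests chosen after seeing the data are listed above. Over all alternatives, 6363 of 6680 values of the genes named by the rule kept direction and side of the threshold (195 weaker, 40 newly past it, 69 moved, 13 reversed), as did 391 of 662 for miRNAs (226, 14, 25 and 6) and 1814 of 2009 for lists (75, 41, 78 and 1). Values named below changed, and unless the construction shows why, the cause was not tested. The miRNA slide block was not run (1 slide), nor were the shControl miRNA comparison with only its 2 groups or without its 1 control array. miRNA normexp correction used the median signal. Without a non-irradiated array the other one is assumed to vary like the other groups. Background limits the dim end: 40 of 231 miRNAs lay at the floor on all arrays.

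Genes called against uninduced cells (main 6727) came to 4245 with normexp, 3934 with median scaling and 339 with spike-in scaling. Against shControl (7249) they came to 963 with spike-in scaling and 4521 with slide averages. For shControl against uninduced cells (980) they came to 178 with normexp, 259 with median scaling, 10 with spike-in scaling, 2541 with spike-in scaling and the scan session as a block, 2161 with the slide as a block, 2006 with the scan session as a block, 549 with only the 2 groups, 145 with slide averages (fewer arrays) and 652 with near-identical arrays averaged. Slides 1 and 3 alone gave 0 and 0 (above), with fewer arrays. Leaving out 1 array gave 639 (without shControl 3) to 1044. Day 6 against day 4 (6777) came to 4057 with slide averages, 3441 on slide 1 and 3094 on slide 2. Genes changed against both controls (5753) came to 3744 with normexp, 3180 with median scaling, 279 with spike-in scaling and 3790 with slide averages.

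Overlaps with irradiation, at day 4 up (1617), came to 154 at a change of at least 1, 903 with normexp, 715 with median scaling, 81 with spike-in scaling and 1047 with slide averages. Down (1711) they came to 123 at a change of at least 1, 1042 with normexp, 112 with spike-in scaling and 1059 with slide averages. At day 6 up (1673) they came to 176, 1039, 689, 81 and 1089 in the order of day 4 up, and down (1804) to 145 at a change of at least 1, 138 with spike-in scaling and 1155 with slide averages.

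miRNAs called against uninduced cells (66) came to 111 with total gene signal, 149 with normexp, 22 without filter, 38 with trend and robust, 18 with the replicate block and 6 with series matrix values. With the percentile over all probes limma called 0. Leaving out 1 array gave 32 (without uninduced 2) to 68. Against the shControl array (40) they came to 73, 26 with quantile normalization, 1 without filter, 7 with trend and robust and 4 with the replicate block. limma called 0 with the percentile over all probes (23 at a raw p below 0.05) and 0 with series matrix values (43). Leaving out an induced array gave 1 (induced 1), 6 (induced 3) and 20 (induced 2).

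miR-15b lost its call against uninduced cells with the percentile over all probes (-0.87, adjusted p = 0.478), quantile normalization (-0.53, 0.130), no filter (-0.65, 0.0552), the replicate block (-0.65, 0.0532) and series matrix values (-0.69, 0.112), in a range of adjusted p from 0.00111 to 0.478. Without any 1 array it measured -0.71 to -0.57 and kept its call. Against shControl it lost the call with the percentile over all probes (-1.09, 0.435), quantile normalization (-0.23, 0.742), no filter (-0.65, 0.195), trend and robust (-0.65, 0.108), the replicate block (-0.68, 0.122), series matrix values (-0.83, 0.217) and without each induced array (-0.67 to -0.63, adjusted p = 0.0791 to 0.107), in a range from 0.0110 to 0.742. In shControl against uninduced cells TACC3 (0.08) measured -0.10 on slide 1 and -0.0285 in the first scan session. SIRT4 (-0.32) passed with the slide as a block (-0.25, adjusted p = 0.0310) and the replicate block (-0.32, 0.0425) and measured 0.0601 with spike-in scaling, with adjusted p from 0.0310 to 0.932 over its alternatives. TACC3 and SIRT4 kept direction and call in every alternative of the 5 other mRNA comparisons.

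Lists past the threshold numbered 4, 4, 5, 8, 11 and 11 in the mRNA comparisons (against uninduced, against shControl, shControl against uninduced, day 4, day 6, day 6 against day 4) and 2 and 2 for miRNAs. With an estimated correlation they numbered 2, 0, 0, 3, 7 and 7, and 0 and 0. With fry they numbered 13, 13, 17, 19 and 17 in the mRNA comparisons other than shControl against uninduced. The miR-15/16 family reversed without filter (-0.11 by median, test upward).

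With spike-in scaling SIRT2 (-0.0343) and SIRT3 (-0.0401) reversed against shControl, CDKN1A (0.0194) in shControl against uninduced cells, SIRT7 (-0.0281) at day 4, SIRT2 (-0.38), SIRT6 (-0.24) and SIRT7 (-0.53) at day 6, and SIRT2 (-0.0877) between the days. With the mean of a gene's probes SIRT3 (-0.00829) reversed against uninduced cells and SIRT5 at day 4 (0.16) and day 6 (0.20). SIRT2 reversed with median scaling at day 6 (-0.0367), MKI67 with normexp between the days (0.13), miR-503 (0.0456) and miR-497 (0.25) with normexp against uninduced cells and miR-497 (0.0642) against shControl. Without scaling between arrays miR-15a (-0.47, against uninduced cells) and miR-29a (-0.0690, against shControl) reversed, and miR-29a with the percentile over all probes (-0.19).

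Besides LMNB1 (above), leaving out 1 array ended the call of SIRT2 against shControl without shControl 1 (0.27), shControl 2 (0.26) or induced 4 (0.26), and of SIRT7 between the days in 5 of 6 cases. MDM2 passed against uninduced cells without uninduced 4 (-0.48), and in shControl against uninduced cells without shControl 2 (-0.67) or uninduced 4 (-0.70). SIRT6 passed there without uninduced 4 (-0.29), SIRT7 passed at day 6 without non-irradiated 1 (0.19) and SIRT3 between the days without day 6 array 3 (-0.23). Against uninduced cells calls were lost without 1 array for miR-21 and miR-7 in 3 of 6 cases, miR-1274a in 2, miR-181a, miR-1974 and miR-200a in 5 and miR-429 in 4. Same-numbered arrays correlated at 0.47, 0.50, -0.53 and 0.67 between shControl and induced cells, 0.19, 0.34, -0.40 and 0.75 between shControl and uninduced cells, 0.27, -0.22 and 0.21 between the days, and 0.76, -0.69 and -0.79 for miRNAs, which shows no shared pairing, and the replicate block called 8156 and 1315 genes in the shControl comparisons.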

Other observations

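4 genes that rose late after irradiation lay at or near the floor before it, and their values varied between the arrays of day 4. PLA2G2F, a secreted phospholipase, was at the floor on both non-irradiated arrays, at -4.01, -3.72 and -2.39 at day 4 and at 0.87, 1.51 and 1.11 at day 6. LGI2 was at the floor on both, then at -3.85, -3.67 and -2.22, then at 0.75, 1.43 and 1.09. IGKV2-24, an immunoglobulin light chain segment, measured -4.93 and -4.01, then -3.41, -3.37 and -1.45, then 0.93, 1.94 and 1.49. CCKBR, a gastrin receptor, was at the floor on both and on 1 array of day 4, at -4.72 and -3.82 on the others, and at -0.63, -0.48 and -0.61 at day 6.

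Arrays induced 1 and 2 differed at 6.82% of 176 probes with at least 5 spots by more than the spread of the spots, and uninduced 1 and 2 at 8.52%, where every other pair within a group differed at 18.8% or more. The uninduced pair had the largest spread of spots (0.18), which lowers its share, and uninduced 1 lay closer to 3 (median difference 0.12) than to 2 (0.14), so this pair does not stand apart. With both pairs averaged limma called 5799 genes against uninduced cells and 6591 against shControl.

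A hypothesis, with its test chosen in advance except for the part without floor values, was that miRNAs inside a gene change with that gene under TACC3 shRNA with doxycycline. Over 64 miRNAs in 53 host genes (36 of them called) the changes against uninduced cells correlated at a Spearman rho of 0.27 (p = 0.0476 from 100000 permutations) and a Pearson r of 0.21 (p = 0.127). Of the miRNAs 11 lay at the floor on every array, and without them rho was 0.30 (43 host genes, p = 0.0465) and r 0.22 (p = 0.151). miR-15b lies in SMC4, a condensin subunit, which measured -0.46, and miR-106b (-0.38), miR-93 (-0.71) and miR-25 (-0.06, adjusted p = 0.769) lie in MCM7, which measured -0.63. Against their hosts went miR-32 (-0.17, host 0.98), miR-505 (-0.25, host 1.28) and miR-425 (-0.45, host 0.48), all named after their values were seen. A link of some miRNAs to their host genes may hold (rho 0.27), but the strand was not used and the Pearson test did not pass.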
